A study of Mus musculus with 2 samples.

How the data were processed

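PolyA RNA of MEL cells treated with 2% DMSO for 5 days was measured by single-end RNA-seq in 2 libraries, 1 group of 2 biological replicates per the labels. The replicate numbers are those of the labels. Both libraries carry the same cell sample identifier there, so the labels do not settle whether the cultures were separate. Per the labels and the submitters' file lists, reads were placed on mm10 and quantified against the GENCODE M4 annotation. The program, aligner and versions are not given in the sources used here.

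The authors deposited 1 gene table and 1 transcript table per library. Expected counts (estimated reads per gene or transcript, not whole numbers where reads are shared) were deposited without scaling, per the file headers. TPM and FPKM were deposited as length-scaled values, also per the file headers, together with posterior means, their SDs and credibility bounds whose level is not given in the sources used here. The percent of a gene's expression held by each transcript was deposited in the transcript tables. FPKM was not used. Estimation splits reads among near-identical copies and transcripts, which makes the values of single copies uncertain, and short genes get high TPM from few reads.

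Symbols, gene classes and coordinates came from GENCODE M21, a later annotation of the same assembly, matched by Ensembl ID: 42462 of 43346 genes matched. The listed symbols without a match (Ahsp, Snhg1, Snhg8, Lincred1) were not analysed here. The tables also hold 26248 rows with numeric identifiers and 97 spike-in rows. They name no gene and stayed out of the count methods and the gene lists, but deposited TPM and the totals of reads include them. The numeric rows held 0.0294% of reads in replicate 1 and 0.0465% in replicate 2, and 0.806% and 1.49% of TPM.

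Depth was 26149725 and 14149299 estimated reads in replicates 1 and 2, with a floor of 0.115 and 0.212 CPM for a gene at 0. Expected counts were rounded for count methods. TMM factors and the common dispersion (intercept only, at least 10 counts in both libraries) were computed with edgeR 4.0.16 and size factors with DESeq2 1.42.0 in R 4.3.3. Log2 ratios used a prior count of 1, and the ratio of TPM a pseudocount of 0.1. With 1 library against 1, ratios between replicates have no test. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9. The median log2(TPM + 1) of each gene list, or its median log2 ratio over members with a mean of at least 10 counts, was compared with 10000 random lists of the same size, drawn from protein-coding genes for levels and matched on mean count in 20 bins for ratios. The spread of a list median over its members was a 95% bootstrap interval (10000 resamples), added after the data were seen. Detection meant at least 1 TPM in both libraries. Pseudogenes with a mean of at least 100 TPM were aligned to protein-coding and mitochondrial transcripts with BLAST+ 2.17.0, and a copy needed at least 95% identity over at least 80% of its length.

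GC content was the TPM-weighted mean over a gene's M21 transcripts, for genes with most of their TPM on matched transcripts. Transcripts were first matched by ID and equal length, which gave a value for 74.1% of genes with a mean of at least 100 counts, below the 80% taken as needed for the check. After its result had been seen (rho 0.766), the match was widened to the ID alone, which gave 98.8% (rho 0.763). Both versions are kept among the alternatives. The GC trend was a lowess curve (span 0.3, 3 iterations) over protein-coding genes with a mean of at least 100 counts.

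The gene lists, the tests and most alternatives were fixed before the data were examined. Lists covered adult, embryonic and theta globins, heme synthesis, heme support and turnover, iron, red cell membrane, red cell enzymes, erythroid transcription factors, late erythroid and mitophagy genes, erythroleukemia and progenitor regulators, Epo receptor signalling, proliferation, G1 cyclins and kinases, cell cycle inhibitors, glycolysis, stress response, apoptosis, long non-coding RNAs, reference genes, ribosomal proteins, mitochondrially encoded protein genes, replication-dependent histones, and markers of 8 other cell types. The rule for named genes took every globin gene, heme synthesis enzyme and erythroleukemia regulator, of each other list the 4 highest and 2 lowest members by mean TPM, the 20 highest protein-coding and 10 highest long non-coding RNA genes, the 10 largest ratios between the replicates in each direction, 30 genes chosen for their transcripts, and the 10 largest differences in leading transcript share. Some genes that this rule takes are not reported here. Alternatives were other pseudocounts, filters, detection limits, scalings, units, backgrounds of random lists and each library alone.

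The steps were tested on simulated data. With 200 genes changed 4-fold at a true coefficient of variation of 0.3, replicate 2 against replicate 1 over 12151 genes, the estimate was 0.320, 89% of changed genes passed 2-fold and so did 11.5% of the others. True values of 0.1 and 0.6 were estimated as 0.167 and 0.581. The 200 changed genes were part of these estimates, so with them present a small spread was overestimated. At 0.6, 43.3% of unchanged genes passed 2-fold. In a simulation of replicate 2 against replicate 1 with a GC trend over 9482 genes, a slope of 0.08 was recovered as 0.0796, a list shifted by 1 on the log2 scale lay at percentile 100, and 5.3% of unshifted lists fell outside the central 95%.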

Results

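MEL cells are a mouse erythroleukemia line, arrested as red cell precursors, in which dimethyl sulfoxide (DMSO) starts hemoglobin synthesis. The libraries came from polyadenylated RNA of MEL cells kept in 2% DMSO for 5 days. There was 1 group with 2 biological replicates by the labels, and no untreated group was analysed here, so every value is a level in treated cells and none is a response to DMSO. Replicate 1 held 26149725 estimated reads and replicate 2 held 14149299. At these depths a gene with no reads could have made up at most 0.115 CPM (counts scaled to library size) in replicate 1 and 0.212 in replicate 2 (3 counts, counting error only). Levels are given as TPM (reads scaled to transcript length and library size), as mean ± SD of the 2 libraries (n = 2). Where the libraries differ, the log2 ratio is that of replicate 2 over replicate 1, with no replicate check and no p-value, since 1 library stands against 1.

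The first question was which genes filled the transcriptome of the treated cells. mt-Atp8, a subunit of the mitochondrial ATP synthase, had the highest level of any protein-coding gene, 102299 ± 8369 TPM. It was followed by the ribosomal protein gene Rps26 at 29038 ± 12234, by the alpha globin genes Hba-a2 at 22778 ± 23691 and Hba-a1 at 14178 ± 6145, by mt-Co1 at 13249 ± 6485 and by the beta globin gene Hbb-bs at 10745 ± 3110.1. Pseudogenes stand outside this ranking. Gm28661, identical to mt-Co2 over its length, had 53164 and 15513 TPM in replicates 1 and 2. Gm10925, identical to mt-Atp6, had 27853 and 30695, and 3 copies of Rpl41 together had 33374 and 14337. Others among the 20 most abundant protein-coding genes were the mitochondrial genes mt-Nd4 (10131 ± 342), mt-Nd2 (7096 ± 934), mt-Cytb (6002 ± 60.9), mt-Nd6 (5629 ± 2134) and mt-Nd1 (4905 ± 599), the ribosomal protein genes Rpl28 (8121 ± 4719.9), Rpl41 (7744 ± 4.62) and the ribosome-bound Rack1 (5979 ± 1221), the elongation factor gene Eef1a1 (8880.0 ± 2862), Ptma (4605 ± 1677), Gm10260 (4424 ± 1989) and the polyA-binding protein gene Pabpc1 (3784 ± 1578). Genes encoded in the mitochondrial genome took 17.0% ± 1.78 of all TPM and 7.92% ± 1.44 of estimated reads, and with their nuclear copies 25.3% ± 3.48 and 12.7% ± 2.43. The 82 cytosolic ribosomal protein genes took 11.5% ± 2.73 of TPM and 5.88% ± 1.21 of estimated reads, and 78 of them reached 1 TPM in both libraries (median 542 TPM, percentile 100), while Rpl39l and Rpl10l had 0 reads in both. Of the 13 protein genes of the mitochondrial genome 12 were detected (median 4905 TPM, percentile 100), the lowest being mt-Nd3 at 610.4 ± 629 TPM and mt-Co3 at 0.5 and 0.94 TPM in replicates 1 and 2. A nuclear copy identical to mt-Co3 over its length had 3311 and 3682 TPM. Protein-coding genes together held 74.7% ± 4.79 of TPM, pseudogenes 21.4% ± 5.14 (and 9.55% ± 2.03 of estimated reads) and long non-coding RNA genes 0.759% ± 0.0989. In all, 11016 genes had at least 1 TPM in both libraries, 9776 of them protein-coding. mt-Atp8 is a short gene that overlaps mt-Atp6, and its share of reads was 1.55% ± 0.0789 against 10.2% ± 0.837 of TPM.

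Globin genes were examined next, since hemoglobin is the product for which MEL cells are treated with DMSO. The adult alpha genes Hba-a1 (chromosome 11, 32283511 to 32284465, plus strand, mm10) and Hba-a2 (chromosome 11, 32296489 to 32297298, plus strand) and the adult beta genes Hbb-bs (chromosome 7, 103826534 to 103828096, minus strand) and Hbb-bt (chromosome 7, 103812524 to 103813996, minus strand) were all strongly expressed, with Hbb-bt at 1744 ± 144 TPM. Globin genes together took 4.96% ± 3.32 of TPM, 2.61% in replicate 1 and 7.31% in replicate 2. Their share of estimated reads was 1.28% in replicate 1 (exact 95% binomial interval 1.27% to 1.28%) and 3.63% in replicate 2 (3.62% to 3.64%), intervals that cover counting error only. Summed alpha globin exceeded summed beta globin in both libraries, 1.56-fold in replicate 1 and 3.93-fold in replicate 2. Within the beta locus Hbb-bs exceeded Hbb-bt 5.21-fold and 7.01-fold. Embryonic globins were low. Hba-x had 1.52 and 8.75 TPM in replicates 1 and 2, Hbb-bh1 0.07 and 1.15 and Hbb-y 0.13 and 0.47, and the embryonic genes Hbb-y and Hbb-bh1 made up 0.00646% ± 0.00636 of beta-like globin TPM. The theta globin genes Hbq1b and Hbq1a stood at 142 ± 89.7 and 3.96 ± 3.24 TPM, and Hbb-bh2 had 0 reads in both libraries. Hba-a1 and Hba-a2 are near-identical copies, and the ratios of alpha to beta use their sum. Between the copies, Hba-a2 was 0.613 times Hba-a1 in replicate 1 and 2.13 times in replicate 2.

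**Figure D1:**
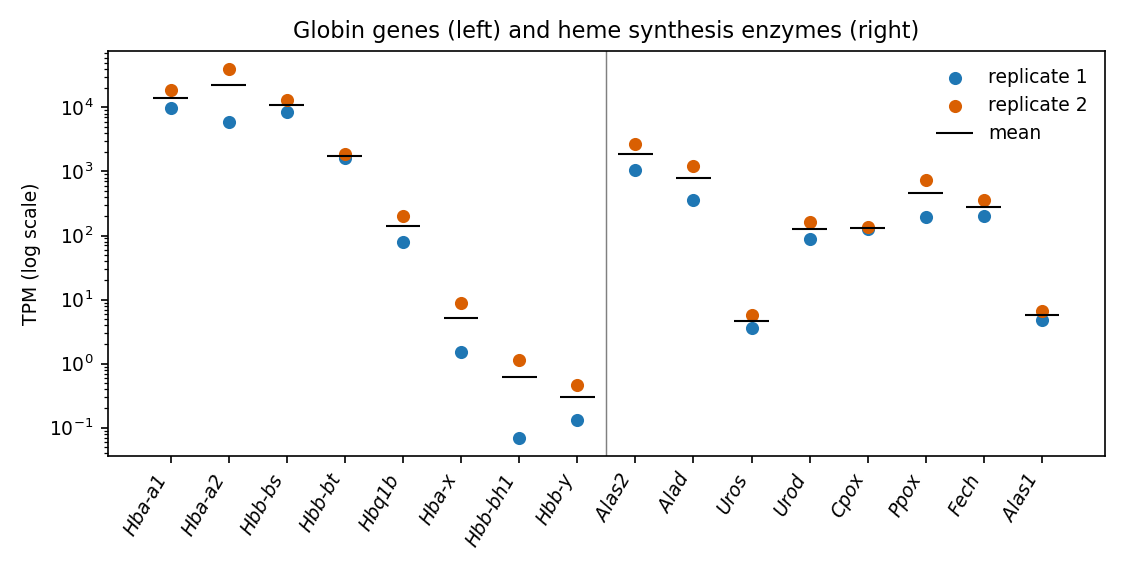
TPM on a log axis of the globin genes other than Hbq1a and Hbb-bh2 (left of the line) and heme synthesis enzymes (right), with a point for each of the 2 libraries and a bar for their mean. Adult globins lie above 1641 TPM and embryonic globins at or below 8.75 TPM, and Alas2 lies far above Alas1 in both libraries.

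All 9 genes for heme synthesis were expressed, with a list median of 182 TPM, at percentile 100 of random lists of protein-coding genes. These random lists, used for all levels, include genes that are not expressed. Against them 20 of 31 lists were above percentile 95. Against genes with at least 1 TPM in either library 14 were. Alas2, the erythroid form of the rate-limiting enzyme, reached 1870.0 ± 1146 TPM, while the housekeeping form Alas1 stayed at 5.77 ± 1.32. Of the Alas2 TPM, 70.4% lay on a 569-base transcript without a coding sequence, which held 45.8% of the estimated reads. Alad followed at 784 ± 609, Ppox at 469 ± 387, Fech, which inserts the iron, at 280.3 ± 116, Cpox at 132 ± 7.73, Urod at 126 ± 54.8 and Uros at 4.65 ± 1.44. All 16 measured genes of heme support and turnover were detected, with a median of 36.2 TPM (percentile 99.99). Among them were Snx3 (348 ± 39.6), Glrx5 (271 ± 17.1), Blvrb (73.5 ± 37.6) and Tmem14c (70.4 ± 14.6) at the top and Slc25a38 (5.85 ± 2.23) and Blvra (4.34 ± 0.495) at the bottom. Of the iron genes 14 of 16 were detected (median 28.1 TPM, percentile 99.97). The ferritin genes led, Fth1 at 2511 ± 643 and Ftl1 at 783 ± 482, before the iron chaperone gene Pcbp2 at 657 ± 141 and the transferrin receptor gene Tfrc at 95.3 ± 42.6, while Trf had 0.38 and 0 TPM in replicates 1 and 2 and Hfe had 0 reads in both.

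Genes of the red cell membrane and its skeleton were all detected, 25 of 25, with a median of 95.4 TPM (percentile 100). The spectrin gene Sptb had 289.8 ± 151 TPM, the adducin gene Add1 255 ± 57.2 and the ankyrin gene Ank1 216 ± 13.4. Of the Ank1 TPM, 63.1% lay on a 416-base transcript that keeps an intron and held 11.7% of the estimated reads. The lowest of the list were Tspo2 at 8.6 ± 1.98 and Bcam at 2.75 ± 1.44. Red cell enzymes were likewise detected throughout, 11 of 11 (median 114 TPM, percentile 100), led by the carbonic anhydrase gene Car1 at 809 ± 95.3, Sod1 at 627 ± 81.7, Gpx1 at 549 ± 271 and Car2 at 506 ± 203, with G6pdx at 7.7 ± 3.82 and Ak1 at 1.8 ± 0.834 lowest. Of the genes tied to late erythroid steps and mitophagy, 13 of 14 were detected (median 17.1 TPM, percentile 99.4). The mitophagy receptor gene Bnip3l led at 263 ± 125, before Mxi1 (40.9 ± 1.29), Trim10 (40.5 ± 12.8) and Fbxo7 (28.2 ± 4.93), while Xpo7 stood at 5.69 ± 0.361 and Alox15 at 0.07 and 0 TPM in replicates 1 and 2.

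Every erythroid transcription factor on the list was expressed, 20 of 20, with a median of 68.8 TPM (percentile 100). Zfpm1, the partner of GATA factors, had 394 ± 168 TPM, Gata1 itself 299 ± 127, Ldb1 295 ± 113 and Hemgn 230 ± 27.6, with Sox6 (12.1 ± 1.15) and Lmo2 (7.02 ± 4.31) lowest. Among regulators linked to erythroleukemia and to progenitors, 10 of 14 reached 1 TPM in both libraries (median 12.3 TPM, percentile 96.2). Myc stood at 154 ± 74.7 TPM, and Spi1, which encodes PU.1, at 82.2 ± 41.3. Cdkn2a had 60.8 ± 39.6, Bmi1 57.7 ± 29.996, Runx1 25.6 ± 7.34, Trp53 20.6 ± 12.8, Myb 19.3 ± 7.74 and Fli1 5.36 ± 0.919. Meis1 (2.05 ± 0.622) and Gata2 (1.98 ± 0.615) were low, Hoxa9 had 1.07 and 0.39 TPM in replicates 1 and 2, and Mycn (0.03 and 0.12), the stem cell factor receptor gene Kit (0.1 and 0.01) and Erg (0 and 0.02) were near 0. Epo receptor signalling genes were detected in 14 of 15 cases (median 14.01 TPM, percentile 98.6), with Epor at 85.6 ± 72.0, Cish at 83.4 ± 78.0, Pim1 at 54.4 ± 13.5 and Ptpn6 at 41.1 ± 0.757, and with Socs3 (2.38 ± 1.34) and Socs1 (0.48 ± 0.382) lowest.

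Genes of the dividing cell were expressed at day 5. All 26 proliferation genes were detected (median 56.7 TPM, percentile 100), with Top2a at 752 ± 573, Mki67 at 662 ± 270.4, the replication clamp gene Pcna at 226 ± 121 and Cdc20 at 134 ± 76.6, and with Tyms (17.7 ± 0.750) and Tk1 (15.4 ± 8.05) lowest. G1 cyclins and kinases were detected in 10 of 11 cases (median 29.0 TPM, percentile 99.9). Ccnd3 had 93.6 ± 67.5 TPM, E2f4 89.1 ± 30.1, Cdk4 70.3 ± 25.4 and Rb1 43.5 ± 18.5, against 7.33 ± 5.13 for E2f1 and 0.58 and 0.2 in replicates 1 and 2 for Ccnd1. Of the cell cycle inhibitors 10 of 11 were detected (median 14.5 TPM, percentile 97.3), among them Gadd45a (272 ± 44.7), Cdkn1b, which encodes p27 (141 ± 51.1), Btg2 (53.2 ± 17.9) and Cdkn2c (30.4 ± 4.2002), with Btg1 (3.53 ± 0.884) and Cdkn2b (1.15 ± 0.368) lowest. Replication-dependent histone genes, whose messages lack a polyA tail, were detected in 7 of 64 cases (median 0.448 TPM, percentile 41.5), with Hist1h2ap at 594 ± 260.1 TPM far above Hist1h2bc (12.5 ± 2.13), Hist2h2be (7.63 ± 1.61) and Hist2h3b (0.41 and 10.5 in replicates 1 and 2). Hist1h2bn and Hist1h3f were among 17 histone genes with 0 reads in both libraries.

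Glycolysis genes had a median of 177 TPM (percentile 100; 14 of 15 detected), with Gapdh at 2469.8 ± 170.1, Aldoa at 1501 ± 616, Pkm at 895 ± 309.7 and Gpi1 at 686 ± 223, while Hk2 stood at 7.96 ± 3.34 and Ldhb had 0 reads in both libraries. Stress response genes were detected in 15 of 17 cases (median 57.9 TPM, percentile 100). Hsp90aa1 had 678 ± 529.7 TPM, Hspa8 577 ± 337, the amino acid response gene Asns 356 ± 18.9 and Sqstm1 337 ± 114, whereas the inducible Hspa1b had 0.4 and 0.17 in replicates 1 and 2 and Hspa1a had 0 reads in both. All 12 apoptosis regulators were detected (median 21.7 TPM, percentile 99.6). Bcl2l11 (113 ± 25.3), Bcl2 (84.1 ± 9.96), Mcl1 (71.1 ± 1.32) and Bid (42.3 ± 10.5) were the highest of them, Pmaip1 (8.69 ± 5.19) and Casp9 (1.67 ± 0.339) the lowest. Reference genes ran from 8880.0 ± 2862 TPM for Eef1a1, 2469.8 ± 170.1 for Gapdh and 559 ± 114 for Actb down to 62.0 ± 24.5 for Ywhaz and 24.8 ± 13.8 for Hprt (median 241 TPM, percentile 100).

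Most markers of other cell types were not detected. Of 79 marker genes, 12 had at least 1 TPM in both libraries. Megakaryocyte and platelet markers accounted for 6 of these, the integrin gene Itga2b at 112 ± 52.5, Pf4 at 16.9 ± 4.50, Gp9 at 7.62 ± 6.59 and Gp1ba at 5.46 ± 2.62 being highest, while Gp6 and Treml1 had 0 reads in both (list median 1.09 TPM, percentile 54.7). Of the granulocyte and macrophage markers 3 of 16 were detected (median 0.0675 TPM, percentile 17.5), Prtn3 at 13.0 ± 9.68, Cd68 at 4.42 ± 1.76 and Cebpa at 3.2 ± 1.90, with Itgam at 0.85 and 2.74 TPM in replicates 1 and 2 and 0 reads for S100a8 and S100a9. Among lymphocyte markers Lck had 3.32 ± 0.990 TPM, Cd3e 2.05 and 0.58, Cd79b 0.72 and 0.25 and Cd3d 0.81 and 0.06 in replicates 1 and 2, and Pax5 and Rag1 had 0 reads (median 0.14 TPM, percentile 27.1). Of the stem and progenitor markers Hlf stood out at 9.11 ± 0.453 TPM, Mecom, Slamf1 and Ly6a had 0.63 and 0.64, 0.69 and 0.45 and 0.59 and 0.42, Cd34 had 0.05 and 0.02 and Procr had 0 reads (median 0.353 TPM, percentile 36.5). The endothelial list (median 0.025 TPM, percentile 19.7) held only Pecam1 above 1 TPM in both libraries, at 5.83 ± 0.332, against 0.52 and 0.86 for Esam, 0.14 and 0 for Tek and 0.01 and 0.04 for Kdr in replicates 1 and 2, and 0 reads for Cdh5 and Cldn5. No gene of the mast cell and basophil list (10 genes, median 0, percentile 0), the fibroblast list (7 genes, median 0.07, percentile 29.2) or the hepatocyte list (7 genes, median 0, percentile 0) did so. Of the mast cell genes Hdc had 0.31 and 0.38 TPM in replicates 1 and 2, Ms4a2 0.11 and 0.39 and Cma1 0.08 and 0.14, and the other 7, among them Cpa3, Tpsb2 and Prss34, had 0 reads. Of the fibroblast genes Col1a1 had 0.39 and 0.52 TPM, Col1a2 0.34 and 0.1, Pdgfra 0.01 and 0.25 and Thy1 0.05 and 0.09, with Col3a1 at 0.01 and 0 and 0 reads for Dcn. Apoa1, at 0.79 and 0.88 TPM, was the hepatocyte gene with reads, and the other 6, among them Alb, Ttr, Afp, Cyp2e1 and Tat, had 0. The embryonic globin list had a median of 0.61 TPM (percentile 49.6), the theta globin list 3.96 (percentile 65) and the adult globin list 12462 (percentile 100).

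**Figure D2:**
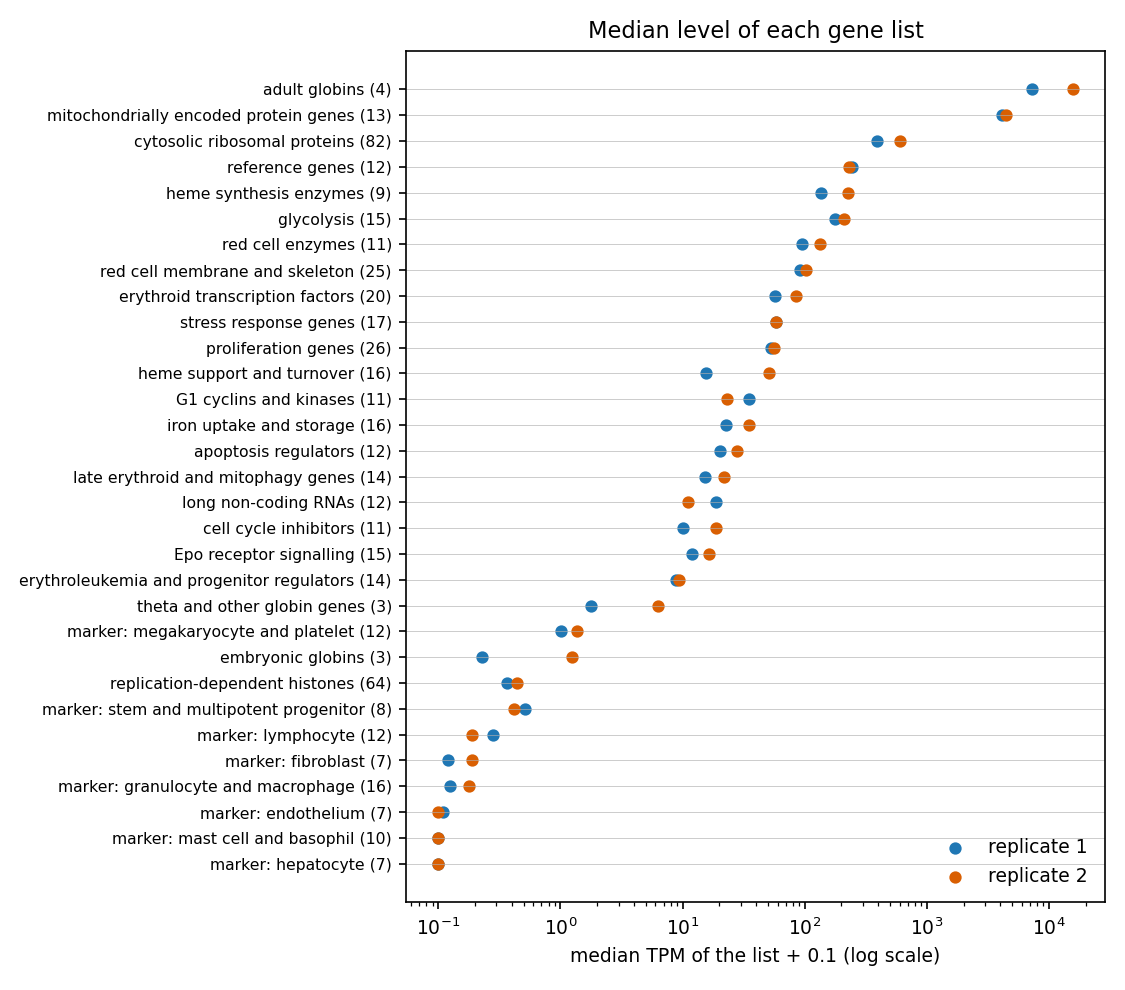
Median TPM of each gene list, plus 0.1 on a log axis, with a point for each of the 2 libraries and the number of genes in brackets. Adult globins lie highest, at 7286 TPM in replicate 1 and 15734 in replicate 2, and mast cell and hepatocyte markers have medians of 0 in both.

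Long non-coding RNAs were a small part of the libraries. Of the 12 listed genes 9 were detected (median 14.6 TPM, percentile 98.2). Gas5, a host of small nucleolar RNAs, had 394 ± 59.9 TPM, the nuclear Malat1 327 ± 225, Neat1 84.4 ± 48.7 and Epb41l4aos 51.96 ± 35.4, while the imprinted Meg3 (0.07 and 0.3 in replicates 1 and 2) and H19 (0.05 and 0) were near 0. Across all genes that the annotation puts in this class, the highest besides Malat1 and Gas5 were Gm42418 at 1664 ± 610 and 1810058I24Rik at 445 ± 9.11 TPM. They were followed by Gm10076 at 246 ± 1.99, Gm14453 at 194 ± 123 and AI662270 at 167 ± 57.0. Then came Gm26825 at 134 ± 9.09, 2410006H16Rik at 114 ± 37.5 and Gm26917 at 93.4 ± 66.2 TPM. Gm42418 and Gm26917 lie next to each other on chromosome 17 (39846958 to 39848788 and 39843013 to 39846341). Whether their reads came from long non-coding RNAs was not tested.

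How far the replicates agree sets the error of all these levels. Heme synthesis enzymes stood higher in replicate 2 in 8 of 9 cases, with a median log2 ratio of 0.65 (percentile 99.6 of random lists matched on mean count), for example Alad at 1.55 and Alas2 at 0.90. Genes of heme support (median 0.66, percentile 99.8), the red cell membrane (0.45, percentile 99.9), glycolysis (0.44, percentile 99.7) and cytosolic ribosomal proteins (0.26, percentile 100) also lay higher in replicate 2. Long non-coding RNAs (-1.40, percentile 0.01) and lymphocyte markers (-1.46, percentile 2.21, 5 genes near the detection limit) lay lower. These 7 of 26 lists were outside the central 95% of random lists, where chance gives 1.3. The adult globin list (0.52, percentile 97.3) and the proliferation list (-0.16, percentile 68.8) were inside it, as were the remaining lists tested.

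The ratio between the replicates followed the GC content of the transcripts. Across 9482 genes Spearman's rho was 0.763, where genes are not independent replicates. Genes below 40% GC had a median log2 ratio of -1.20 and those above 60% had 1.12. With the GC trend removed, an alternative chosen after seeing the data, 4 lists were outside the central 95%. The heme synthesis enzymes kept a median of 0.35 (percentile 98.8), the ribosomal proteins had 0.030 (percentile 99.2) and the lymphocyte markers -1.83 (percentile 0.66). The mitochondrially encoded protein genes, at 37.1% median GC, went from -0.29 (percentile 66.6) to 1.05 (percentile 100). Of the 9482 genes 442 lay in the class below 40% GC, so the trend rests on few genes there. Reads assigned to nuclear copies of the mitochondrial genes are left out of this list. The red cell membrane, heme support, glycolysis and long non-coding RNA lists had medians of 0.087, 0.22, -0.043 and -0.23 and were inside the central 95%.

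**Figure D3:**
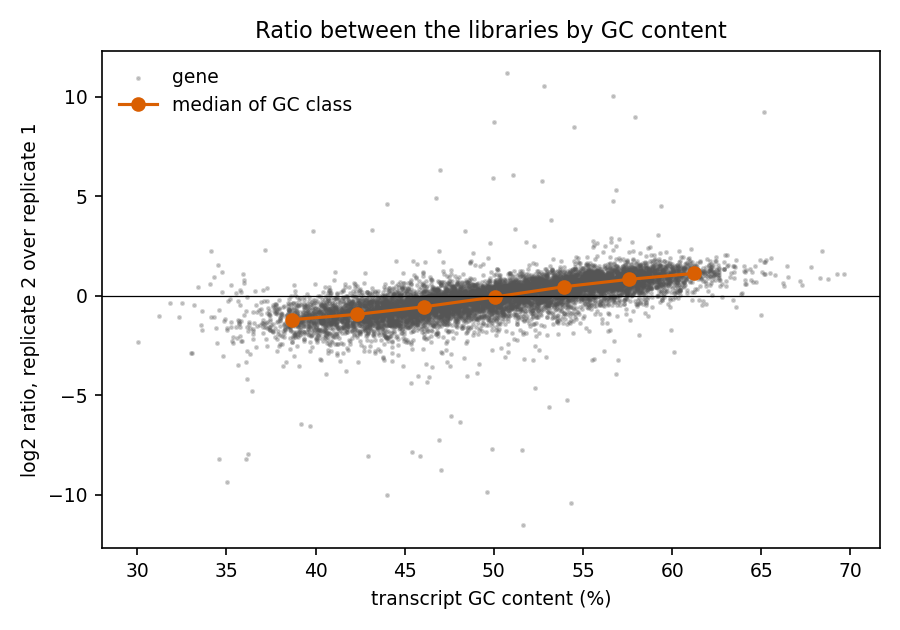
Log2 ratio of scaled counts, replicate 2 over replicate 1, against transcript GC content in percent, with a grey point for each gene that has a symbol among the 9482 genes compared, and orange points for the medians of 7 GC classes. The class medians rise from -1.20 to 1.12.

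Over single genes, Pearson's r of log2(TPM + 1) between the libraries was 0.884 and Spearman's rho 0.880 across 12675 genes. The biological coefficient of variation by edgeR was 0.427. In the check for 1 library standing as both replicates, the chi-square per degree of freedom between the counts was 285. Of 9597 genes with a mean of at least 100 counts, 2546 differed by at least 2-fold, 1006 higher and 1540 lower in replicate 2. By TPM as deposited the split was 1780 higher and 1131 lower, around a median log2 ratio of 0.17 in place of -0.067. With the GC trend removed it was 832 of 9482 genes. The largest differences were mostly in pseudogenes, whose reads are hard to assign between near-identical copies. Gm14414 had 4551 and 0 estimated reads in replicates 1 and 2, Gm4613 2122 and 0, Gm9836 1570.1 and 0, Pgk1-rs7 1447 and 0, Gm14599 994 and 0, Gm4322 669.7 and 0, Gm28439 456 and 0, Rex2 448 and 0 and Cbx3-ps7 408 and 0, besides 1 gene without a symbol. In the other direction Rps27 had 0 and 1524, Rpl27-ps3 0 and 969.5, Gm10231 0 and 683, Gm22133 0 and 399, Rps2-ps6 2.9 and 1328, Gm10123 0 and 283, Gm20388 0 and 230.1, Gm20537 7.32 and 425, Gm12435 4.91 and 268 and Gm10254 16.0 and 680.0.

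The last question was which transcripts of erythroid genes were used. Gata1-201 made up 96.9% ± 2.04 of the TPM of Gata1 (SD, n = 2) and Pkm-201 96.2% ± 1.62 of that of Pkm, while Fech and Klf1 have 1 transcript in the tables and Kit had too few reads for a share. Smaller but similar shares in both libraries were found for Ldb1-201 (81.5% and 74.9% in replicates 1 and 2), Bach1-201 (88.8% and 77.2%), Spi1-204 (75.0% and 84.4%) and Slc25a37-203 (53.6% and 59.8%). Of 27 genes with several transcripts, 20 had the same leading transcript in both libraries, the exceptions being Tfrc, Epb41, Lmo2, Myb, Ikzf1, Nfe2 and Uros, where the transcript given has the highest mean share, and 11 differed in its share by over 20 percentage points. The transferrin receptor gene was among the latter, with Tfrc-201 at 14.8% and 79.6%, as were Epb41-215 (9.19% and 72.4%), Lmo2-208 (82.4% and 0.03%), Myb-201 (70.5% and 12.6%), Ikzf1-204 (75.8% and 28.4%), Tal1-201 (98.4% and 69.1%), Zfpm1-201 (55.6% and 84.0%), Bnip3l-205 (62.7% and 34.3%), Alad-201 (64.0% and 90.6%), Nfe2-210 (46.4% and 21.5%) and Ank1-211 (75.5% and 50.7%). Other leading transcripts were Alas2-204 (61.4% and 79.4%), Slc4a1-203 (92.5% and 77.9%), Pklr-203 (54.5% and 69.8%), Bcl2l1-201 (79.2% and 59.8%), Runx1-201 (72.5% and 54.5%), Slc11a2-207 (59.6% and 42.4%) and Uros-206 (40.4% and 37.1%), where Uros-207 led in replicate 2 with 46.1% and had 0% in replicate 1. By annotation the leading transcripts of Alas2, Slc4a1, Epb41 and Bnip3l are processed transcripts without a coding sequence, and those of Slc25a37, Ank1 and Uros keep an intron. By expected counts in place of TPM (mean of the libraries) their shares were 45.8% for Alas2, 32.9% for Slc4a1, 52.2% for Epb41, 24.6% for Bnip3l, 65.1% for Slc25a37, 11.7% for Ank1 and 60.3% for Uros, and those of Pklr-203 and Slc11a2-207 17.0% and 13.9%. In 22 of the 27 genes the same transcript led by expected counts, while Pklr-202 (77.6%), Slc4a1-201 (67.1%), Ank1-213 (49.3%), Slc11a2-201 (46.5%) and Bnip3l-201 (69.4%) led in the others. Across 5523 genes with several transcripts, 70.6% had the same leading transcript in both libraries (exact 95% binomial interval 69.4% to 71.8%, which takes genes as independent draws). The largest differences in share were in Fam219b-201 (100% and 0%), Homer2-201 (0.01% and 100%), Tmem184b-202 (100% and 0.19%) and Lrsam1-202 (0% and 99.6%). They were followed by Wdr41-201 (1.38% and 99.5%), Tdrd3-202 (97.7% and 0%), Brd3-201 (99.8% and 2.94%), Gm7292-201 (100% and 3.38%), Clasp2-203 (99.0% and 3.95%) and Rbbp8-201 (5.55% and 100%).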

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

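The length test with GC content held and the repeat of the erythroid programme test with the GC trend removed were chosen, and the spread of the list medians was added, after their results were seen, and the match of transcripts behind the GC tests was widened after the first result.

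Signals stood in rows outside the gene measurement, above the limit that 0 counts allows. The spike-in row of the phiX174 phage had 61 estimated reads in replicate 1 and 0 in replicate 2. The most abundant of the rows with numeric identifiers, 156 bases long, had 2735 estimated reads in replicate 1 and 1009 in replicate 2.

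The replicates differed in 2546 of 9597 genes by at least 2-fold. Lower depth of replicate 2 is argued against, since 28.8% of the 3743 genes with at least 1000 counts differed as much. A GC bias between the libraries may account for much of it, as the log2 ratio followed GC content with a rho of 0.763. The data do not say which library it lies in. With the trend removed 832 genes, 8.77% of 9482, differed, and 9.01% of those with at least 1000 counts. In the simulation at a coefficient of variation of 0.3, 11.5% of unchanged genes passed 2-fold, and at 0.1 it was 0.0213%. The coefficient found with the trend removed, 0.310, was estimated from these same 2 libraries. The simulation near that value therefore cannot tell whether another source is needed. Transcript length had a rho of -0.120, between the bounds set in advance, and is argued against by the value of 0.0291 with GC content held. For the list shifts, a culture further along the erythroid programme was to put all 4 erythroid lists outside the central 95% of random lists. At least 2 of the 4 inside it were to count against this cause. Outside lay 2 (heme synthesis and red cell membrane), and 1 (heme synthesis) with the GC trend removed, so the bound against it was met. The proliferation list (-0.16), which was to shift the other way, also lay inside. Of the erythroid lists inside, only the late erythroid list (median -0.085, interval -0.21 to 0.41) stayed under its limit of 0.48 by more than the spread of its members. Adult globins (0.52) lay just under 0.53, with an interval that passes it. Within that spread the cause stays open.

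Alpha over beta globin was 2.52 times as high in replicate 2 as in replicate 1. A GC bias cannot be told apart from another source. The alpha genes averaged 57.3% GC against 51.4% for beta. The log2 difference in counts was 1.28, and 0.69 remained with the trend removed, just under the bound of 0.7 that would have excluded a GC bias. The fitted trend thus took away part of the difference and not all of it. With the trend removed, the log2 ratio was 1.77 for Hba-a2 and -0.20 for Hba-a1, at 56.9% and 57.6% GC. The split of reads between these near-identical copies is uncertain, so these 2 values do not decide the question. For the alpha to beta ratio no biological explanation was tested, since the design has 1 group.

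Pseudogenes took 21.4% ± 5.14 of TPM and 9.55% of estimated reads. Reads shared with parent genes are a candidate explanation, since 95.5% of that TPM lay on near-identical copies, 112 of the 113 pseudogenes above 100 TPM. Transcription of the copies themselves was not tested.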

How the results depend on the processing

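No paired analysis was possible because there is 1 group. The GC alternatives and the addition of nuclear copies were chosen after seeing the data. The counts of detected genes, list members and lists with high levels stayed within 1.5 times under each alternative run for them. Lists with high levels were 20 of 31, but 14 against random lists of genes with at least 1 TPM in either library. The globin share, alpha to beta ratio and embryonic share stayed within 1 SD under other units and denominators. This limit is wide, as the 2 libraries differ: the globin share was 2.45% in expected counts against 4.96% of TPM, with an SD of 3.32. In single libraries the globin share, alpha to beta ratio and embryonic share ran from 2.61 to 7.31%, from 1.56 to 3.93 and from 0.00196 to 0.0110%. Pearson's r was 0.823 with a pseudocount of 0.1, 0.961 with no filter, where genes at 0 in both libraries enter, and 0.898 on posterior means. The coefficient of variation was 0.557 with no filter, 0.426 without globin and mitochondrial genes, 0.310 with the GC trend removed and 0.315 with GC from transcripts of equal length only. Genes differing 2-fold were 832 and 625 under these GC settings, the second on fewer genes (7108), and shifted lists 4 and 3. The glycolysis list turned from 0.44 to -0.043 and -0.17, and the red cell membrane list from 0.45 to -0.010 under the second, where the lymphocyte and ribosomal lists also came inside the central 95% and the histone list went outside (0.85), on fewer genes. By TPM, 9 lists were outside, with erythroid transcription factors (0.77) and red cell enzymes (0.84) added, and the late erythroid median, inside in both, was 0.50 in place of -0.085. In expected counts, protein-coding genes held 88.4% and mitochondrial genes 7.92%, and mitochondrial genes with nuclear copies 25.3% of TPM and 12.7% of expected counts. At 5 TPM, 5 other-cell markers were detected. The same leading transcript was found in 79.4% of genes by expected counts. The median share of the leading transcript over the chosen genes, 69.8%, was 72.4% to 75.0% in single libraries. Apart from these constructions the cause was not tested. Depth limits the embryonic globins, with 3 and 13 estimated reads for Hbb-y plus Hbb-bh1 in replicates 1 and 2.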

Other observations

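In the deposited estimates, pseudogene copies of some abundant genes held many reads. For Npm1, a nucleolar protein gene, 56.3% of the estimated reads of gene and copy lay on the copy Gm14681 in replicate 1 and 7.25% in replicate 2. For Rps28 the copies held 96.3% and 95.7%, for Hmgb1 94.9% and 88.1%, for Rpl17 94.1% and 52.4%, and for Gapdh 16.4% and 26.8%. For mitochondrial genes, the nuclear copy held 99.98% and 99.97% of the reads of gene and copy for mt-Co3. It held 98.0% and 98.8% for mt-Co2 and 16.2% and 55.9% for mt-Nd2. The level of the named gene alone leaves these reads out, and whether they came from the gene or from the copy was not tested. These families were chosen after their values were seen.

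Summing gene and copies (those with a mean of at least 100 TPM) changed the difference between the libraries for some of them. On the sums, with the GC trend not removed, the log2 ratio of replicate 2 over replicate 1 was -3.51 for Npm1, -2.10 for Hmgb1, -2.00 for mt-Co2 and -1.89 for Rpl17. For the gene alone it was -2.43, -0.87, -2.66 and 1.11. The sum gave 0.44 for mt-Nd2, against -0.48 for the gene alone, and -1.26 for mt-Co1 and -0.46 for Rpl41. It was 0.11 for Gapdh, 0.11 for Rps28, -0.062 for mt-Co3 and -0.017 for mt-Atp6.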
